A study of Mus musculus with 32 samples.

How the data were processed

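Gene expression was measured by RNA sequencing in 32 mouse libraries. RNA was purified with a Qiagen RNeasy kit with DNase treatment and made into libraries with an Illumina TruSeq kit, per the labels' protocols. Base calling by CASAVA 1.8.2, alignment by Novoalign 2.07.03 and the genome build mm9 are per the submitters' processing notes alone, and the program that counted reads is not given in the sources used here. The authors deposited 1 table of RPKM values for mouse transcripts, 1 column per library, named by UCSC transcript identifiers. Each column was matched to its library by its title, and no column was left over. A second deposited table, of human tumours on microarrays, was not analysed here. The groups were taken from the labels and the series' design text: clear cell sarcoma by initiating Cre (5, 4, 2 and 2 libraries), osteosarcoma (7, in 4 Col1Cre and 3 Prx1Cre libraries by title), synovial sarcoma (6) and control (6). The labels give no batch, date or animal. Some titles share a number, N123 in 2 TATCre libraries, 37 in 3 and 39 in 2 synovial sarcoma libraries, and nothing says whether these came from the same animal. The p-values therefore measure the spread between these libraries, part of which may be technical.

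RPKM values are not counts, so the tests ran on log2(RPKM + 1). A pseudocount of 1 understates the change of transcripts with a low RPKM. It can overstate that of very short transcripts, where each read is worth many RPKM and values are listed at 0. Every fold change below is on that scale. The main test was limma with an intensity trend (eBayes with trend, two-sided), with Benjamini-Hochberg adjustment and a threshold of 0.05 on the adjusted p. The comparisons of tissue types used all 32 libraries in 1 model of 4 types and the 15230 transcripts with an RPKM of at least 1 in at least 6 libraries. The comparisons of initiating Cre used the 13 clear cell sarcomas and the 15195 transcripts with an RPKM of at least 1 in at least 2 of them. The comparison of osteosarcoma groups used the 7 osteosarcomas and the 12623 transcripts with an RPKM of at least 1 in at least 3. Sets that set a tumour type apart were at least 2-fold higher, past the test, in all 3 contrasts of that type. No covariate was used, since the labels give none. The groups, tests, filters, alternatives and the rule for named transcripts were fixed before the data were examined, and the exceptions are named as added.

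The rule for named transcripts took, for each comparison, the 10 largest positive and the 10 largest negative log2 fold changes among calls with a mean RPKM of at least 5 in the higher group and no overlap between the libraries of the 2 groups. It also named Rb1, Trp53, Ewsr1, Atf1 and Ss18, members of 30 gene lists and the 10 leading transcripts of each set. Of these genes, the titles name only Rb1 and p53 (Trp53). The files do not pair the identifiers with gene names, and no such table was used here. The named genes, the 30 lists and their camera tests were therefore left out, and the text prints the first 2 higher and the first 2 lower transcripts of clear cell sarcoma against the controls. Where transcripts of 1 locus overlap, the counting could have split or shared their reads.

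Depth was recovered from the table itself. In each library the RPKM of a transcript is a whole number of reads times a step set by transcript length and library depth. Ratios between libraries over the 500 lowest shared transcripts gave the relative depths, and at least 96.8% of these ratios were ratios of whole numbers within 1e-06 on the natural log scale. The scale at which the lengths are whole numbers of bases gave the denominators, 8.11 to 13.1 M reads, with 99.9% of 14095 lengths whole. Whole reads and a length followed for 16396 of the 16398 transcripts above 0 in at least 6 libraries. The median recovered length was 1207 bases over these and 1109 over the tested transcripts, and the shortest was 2 bases. What the authors' lengths stand for is not given in the sources used here. Tested on simulated RPKM of 6000 transcripts, the method found a length for 5901, had all reads right in 99.9% of these and missed the denominator by at most 4.59e-05%. The simulation held no transcripts under 100 bases and set no further low values to 0. Recovery of very short lengths was therefore not checked. Zeros were counted against the reads of the other libraries of a group. Sampling alone would give 0 in 0.00454% of values with 10 expected reads, and 14.2% of values with a median of 10 to 20 were listed at 0, but a spread between animals adds zeros too. The closest pair of libraries, the controls Chest1 and Chest2, was therefore used in an added test. Of 2745 values with 20 to 30 reads in 1 of the 2, 135 were listed at 0 in the other and 0 had 1 to 4 reads there, and of 3702 values with 10 to 20 reads, 591 were listed at 0 and 33 had 1 to 4 reads. A spread between libraries would give values of 1 to 4 reads before it gives 0, so part of the low values appears to have been listed at 0 before deposit. A plain minimum of reads is not the rule, since 11489 values of 1 to 4 reads are listed over the 32 libraries, and the sources used here do not give the rule.

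Replicates were compared by a chi-square of recovered reads between libraries of a group. The controls Chest1 and Chest2 were the closest pair, at 1.83 per degree of freedom, against 23.9 to 194 for the other pairs of controls. The labels do not say whether they are separate animals, so both were kept as labelled, and their average was an added alternative, with 7315 calls for clear cell sarcoma against the controls. Comparisons against the same controls were set beside 20 simulations of unchanged groups, the overlap of independent lists and 10 splits of the controls. The nearest library was found by Spearman correlation, with 100000 permutations of the labels. The share of control profile in a tumour library was the median, over transcripts of at least 100 bases that differed at least 8-fold between its type and the controls, of its position between the mean of the other tumours and the mean of the controls. The other tumours were those of its type, and for each Bmi1IRESCreERT2 library those of the other Cre groups only.

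The tests were checked on simulated data in which 100 transcripts changed 2-fold and 100 changed 4-fold. For clear cell sarcoma against the controls, limma recovered 28 and 72 with 3 false calls, and for clear cell sarcoma against synovial sarcoma 29 and 75 with 2 false calls. For TATCre against Rosa26CreER it recovered 9 and 59, and for Prx1CreERT2 against Bmi1IRESCreERT2 1 and 21, with 3 false calls in each. For the 2 osteosarcoma groups it recovered 0 and 0.

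The alternatives fixed in advance were a pseudocount of 0.1, no filter, an RPKM filter of 5, quantile normalization, median ratio scaling, library weights, leaving out each library in turn, the controls without Bone3, fits on other sets of libraries, averaging of libraries that share a title number, and a replicate block. Those added after seeing the data were limma voom on the recovered reads, transcripts above 0 in every library, transcripts of at least 100 bases, Chest1 and Chest2 averaged, Pearson correlation, other filters for the nearest library, and leaving out 4 libraries in doubt (the osteosarcoma Prx1Cre 42, the synovial sarcoma 44, the control Chest3 and the clear cell sarcoma TATCre N123-Rleg). Software was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, numba 0.67.0 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1.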

Results

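RNA was sequenced from 32 mouse libraries of 4 tissue types, made up of 13 clear cell sarcomas, 7 osteosarcomas, 6 synovial sarcomas and 6 control samples. Clear cell sarcoma is a soft tissue tumour that in patients carries a fusion of EWSR1 with ATF1, osteosarcoma is a tumour that forms bone, and synovial sarcoma carries a fusion of SS18 with an SSX gene. The clear cell sarcomas had been started with Cre, a DNA recombinase, delivered in 4 ways. Rosa26CreER started 5 of them, TATCre 4, Prx1CreERT2 2 and Bmi1IRESCreERT2 2. CreER and CreERT2 are forms of Cre that tamoxifen switches on, expressed from the gene named before them, and TATCre is a Cre protein that enters cells. The osteosarcoma titles name Rb1 and p53 together with Col1Cre in 4 libraries or Prx1Cre in 3. All 6 synovial sarcoma titles begin with Myf5-SSM2/PLUC. Rb1 and p53 stand in the osteosarcoma titles only, and the tumour types share no such title. A difference between tumour types therefore cannot be told apart from one of the genotype or Cre that the titles name. Of the controls, 5 are titled Chest and 1 Bone, and the labels do not say which tissue these were.

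The deposited table gave an RPKM value, the reads of a transcript scaled by its length and by the reads of the library, for 55419 transcripts. Of these, 35628 (64.3%) were listed at 0 in all 32 libraries and 8594 were above 0 in all of them. The steps of the low values gave the depth of each library, which was 10.1 ± 1.26 M reads (megareads; SD, n = 32; range 8.11 to 13.1). Depth was 9.54 ± 1.22 M reads in clear cell sarcoma (n = 13), 10.6 ± 0.945 in osteosarcoma (n = 7), 10.3 ± 1.72 in synovial sarcoma (n = 6) and 10.3 ± 1.02 in the controls (n = 6). Between 11894 and 15576 transcripts per library were above 0. A value of 0 was frequent where few reads were expected. Where the other libraries of a group had a median of 10 to 20 reads, 14.2% of the values were listed at 0, against 0.103% at 100 to 1000 reads. A value of 0 is therefore given below as listed at 0, not as absence. Very short transcripts weighed more in the RPKM sums than in the reads. The 1603 transcripts with a recovered length under 100 bases (10.5% of the 15230 tested) carried 27.03% to 48.7% of a library's summed RPKM and 0.678% to 1.29% of its reads. The files name transcripts by UCSC identifiers and do not pair these with gene names. The genes that the naming rule tied to these models or to the fusions in patients (Rb1, Trp53, Ewsr1, Atf1 and Ss18) were therefore not looked up. Only 2 identifiers that rose and 2 that fell are printed.

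The first comparison asked which transcripts separate the clear cell sarcomas from the control tissue. The tumours differed from the controls at 7772 of the 15230 tested transcripts, 5312 higher and 2460 lower. Among these, 3827 were at least 2-fold higher and 1869 at least 2-fold lower, and 555 and 534 were at least 8-fold higher or lower. Transcript uc007equ.1, with a recovered length of 3083 bases, rose most under the naming rule, with 1212 ± 636 RPKM (SD, n = 13) in clear cell sarcoma and 1.64 ± 0.851 in the controls (n = 6). Its log2 fold change was 8.68 (SE 0.55, limma adjusted p = 3.15e-13). Its level was 19.3 ± 37.7 RPKM in osteosarcoma (n = 7) and 3.47 ± 1.84 in synovial sarcoma (n = 6). Transcript uc009czd.1, of 2073 bases, had a median of 443 RPKM in clear cell sarcoma (range 140.0 to 638, n = 13), whereas the highest of the other 19 libraries had 1.34. Its log2 fold change against the controls was 7.85 (SE 0.29, limma adjusted p = 1.38e-18). Transcript uc009kic.1, of 480 bases, had 64.1 to 2057 RPKM in the controls and was listed at 0 in 6 of the 13 clear cell sarcomas, of which the highest had 41.6. Its log2 fold change was -7.78 (SE 0.88, limma adjusted p = 3.08e-08). Transcript uc007gaj.2 had 9291 to 28717 RPKM in the controls and was listed at 0 in 9 of the 13 tumours, of which the highest had 1535 (log2 fold change -11.34, SE 1.75, limma adjusted p = 4.31e-06). The recovered length of uc007gaj.2 was only 3 bases, so its RPKM stands for far fewer reads than the same RPKM of a longer transcript. On so short a transcript each read is worth many RPKM. A value listed at 0 therefore inflates its fall on the scale of log2(RPKM + 1). The size of its log2 fold changes, here and below, is not reliable.

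The balance of higher and lower calls depended on how the libraries were scaled. With the deposited RPKM the median log2 fold change of clear cell sarcoma against the controls was 0.35. Scaling each library by its median ratio shifted that median by -0.36 and gave 3549 higher and 3913 lower transcripts, and quantile normalization shifted it by -0.29 and gave 3896 higher and 3614 lower.

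Clear cell sarcoma was next compared with the other tumour types. Against osteosarcoma, 4854 of the 15230 transcripts differed, 2759 higher and 2095 lower in clear cell sarcoma, and 1842 and 1319 of these by at least 2-fold. Against synovial sarcoma, 3403 differed, 864 higher and 2539 lower, and 695 and 1678 by at least 2-fold. The transcripts uc007equ.1 and uc009czd.1 were among those higher than in both other tumours. Their log2 fold changes were 7.08 (SE 0.52, limma adjusted p = 1.53e-11) and 7.78 (SE 0.28, limma adjusted p = 3.88e-19) against osteosarcoma, and 7.95 (SE 0.55, limma adjusted p = 7.06e-13) and 7.88 (SE 0.29, limma adjusted p = 2.44e-19) against synovial sarcoma. The split against synovial sarcoma moved with the scaling. Median ratio scaling gave 1281 higher and 1600 lower transcripts, still more lower than higher, whereas quantile normalization turned the direction to 1765 higher and 1405 lower. Averaging the synovial sarcoma libraries that share the title number 37 or 39, and the TATCre libraries that share N123, lowered the count against synovial sarcoma to 1129.

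The other tumours were set against the same controls and against each other. Osteosarcoma differed from the controls at 6041 transcripts, 4057 higher and 1984 lower, of which 3058 and 1595 changed at least 2-fold. Synovial sarcoma differed at 6579, 5563 higher and 1016 lower, of which 4253 and 860 changed at least 2-fold. Osteosarcoma and synovial sarcoma differed from each other at 4179 transcripts, 866 higher and 3313 lower in osteosarcoma. The transcripts uc007gaj.2 and uc009kic.1 were also lower in osteosarcoma than in the controls (log2 fold change -7.48, SE 1.97, limma adjusted p = 0.00303, and -6.89, SE 0.99, limma adjusted p = 3.52e-06). In synovial sarcoma neither passed the test (log2 fold change -1.61, SE 2.04, limma adjusted p = 0.552, and -2.11, SE 1.03, limma adjusted p = 0.0985), and in both the library 39-9, with 53200 and 1660 RPKM, stood far above the other synovial sarcomas. Transcript uc007equ.1 was higher in osteosarcoma than in the controls (log2 fold change 1.60, SE 0.62, limma adjusted p = 0.0386), with 104.5 RPKM in the library Col1Cre 22 and at most 10.3 in the other 6. Transcript uc009czd.1 did not pass the test in either comparison (log2 fold change 0.07, limma adjusted p = 0.917 in osteosarcoma, and -0.03, limma adjusted p = 0.954 in synovial sarcoma).

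These splits also moved with the scaling. Median ratio scaling shifted the median log2 fold change by -0.27 in osteosarcoma and by -0.55 in synovial sarcoma against the controls, and by 0.23 in osteosarcoma against synovial sarcoma. It gave 2743 higher and 3168 lower transcripts in osteosarcoma, 2622 higher and 2330 lower in synovial sarcoma, and 1511 higher and 2215 lower in osteosarcoma against synovial sarcoma. Quantile normalization gave 3082 higher and 2727 lower, 2592 higher and 2640 lower, and 2016 higher and 1762 lower in the same 3 comparisons. The libraries that share a title number (37 and 39, and the TATCre N123) were also averaged in 1 fit. There, 2094 transcripts differed between osteosarcoma and synovial sarcoma and 4254 between synovial sarcoma and the controls.

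**Figure D1:**
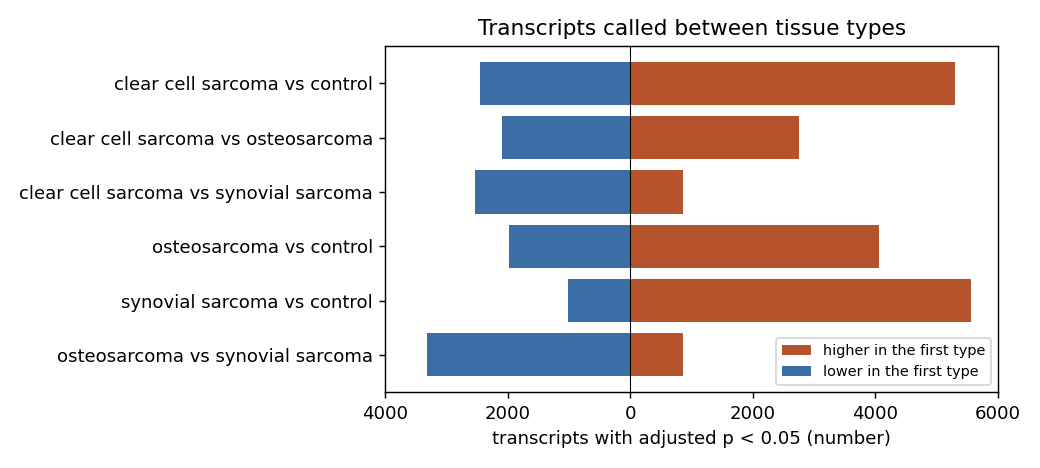
Transcripts called higher or lower in each of the 6 comparisons of tissue types with the deposited RPKM (bars, number of transcripts out of 15230 tested, limma adjusted p under 0.05). Clear cell sarcoma against the controls has the longest pair of bars, with 5312 higher and 2460 lower transcripts.

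Transcripts that set 1 tumour type apart were defined as at least 2-fold higher, past the test, than in each of the other 3 tissue types. There were 482 such transcripts for clear cell sarcoma, 336 for osteosarcoma and 697 for synovial sarcoma. Independent lists of these sizes would share 21.1, 11.2 and 75.9, and 20 simulations of unchanged transcripts gave none in any set. The 3 contrasts of a type share its libraries, so they are not independent lists, and the simulations held no difference in any contrast. Neither value therefore tells how many transcripts are particular to 1 type. The mean log2(RPKM + 1) of the clear cell sarcoma set was 4.201 to 4.93 in the 13 clear cell sarcomas and 1.29 to 2.28 in the other 19 libraries. The mean of the osteosarcoma set was 4.62 to 5.38 in 6 osteosarcomas, 2.88 in the osteosarcoma library Prx1Cre 42 and 1.62 to 2.98 in the libraries of other types. The mean of the synovial sarcoma set was 3.19 to 4.62 in the 6 synovial sarcomas and 0.929 to 1.96 elsewhere. Each set was chosen on these libraries, so the means describe it and are no separate test. A further 642 transcripts were at least 2-fold higher in the controls than in each tumour type, and 1502 were lower. The 642 carried 12.5% to 14.7% of the summed RPKM in the 6 controls, 11.7% in the osteosarcoma library Prx1Cre 42 and 1.55% to 6.68% in the other 25 tumours. The high share in Prx1Cre 42 does not extend to the whole set, whose mean log2(RPKM + 1) was 3.28 there, 1.84 to 3.35 in the other osteosarcomas and 5.06 to 5.66 in the controls. The synovial sarcoma set was the one most sensitive to the scaling, with 410 transcripts after quantile normalization and 482 after median ratio scaling. With the libraries that share a title number averaged, the sets of clear cell sarcoma, osteosarcoma and synovial sarcoma had 291, 185 and 314 transcripts.

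**Figure D2:**
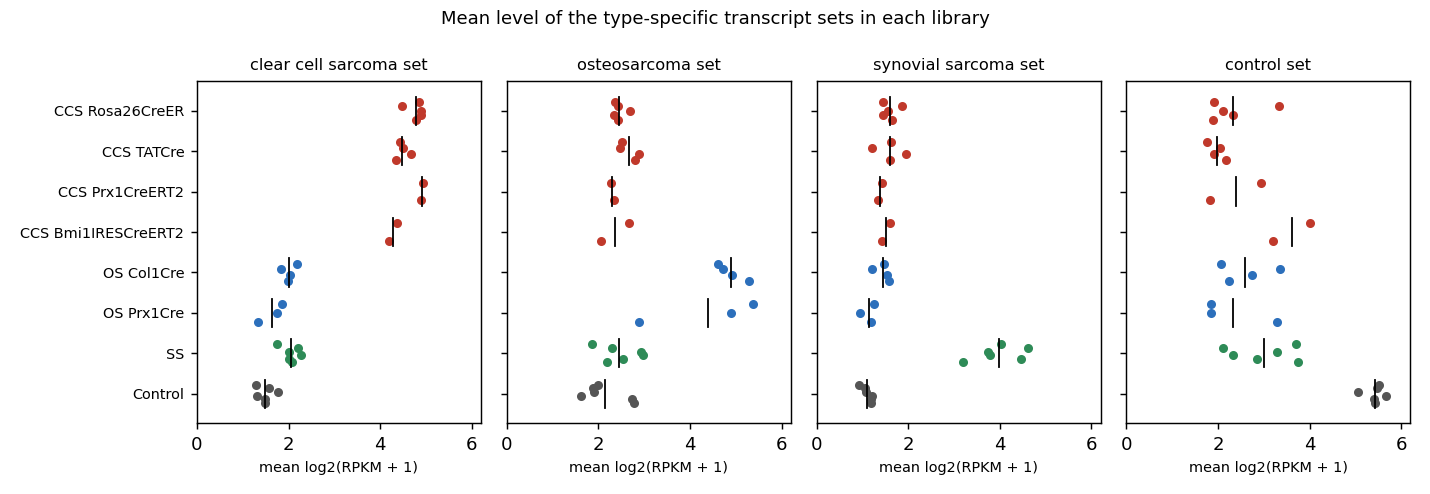
Mean log2(RPKM + 1) per library (points, by group) of the transcripts that set clear cell sarcoma, osteosarcoma or synovial sarcoma apart. Clear cell sarcomas lie between 4.201 and 4.93 on their own set, and the osteosarcoma library Prx1Cre 42 lies at 2.88 on the osteosarcoma set, below the other 6 osteosarcomas.

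The tumour types were compared for the transcripts that changed against the controls in more than 1 of them. Clear cell sarcoma and osteosarcoma had 2840 higher and 1447 lower transcripts in common, where independent lists would share 1415 and 320.5, and 60 changed in opposite directions. Clear cell sarcoma and synovial sarcoma shared 3759 higher and 947 lower transcripts (1940 and 164 for independent lists), and osteosarcoma and synovial sarcoma shared 2789 and 801 (1482 and 132). All 3 tumour types were set against the same 6 controls, which alone creates a correlation. Across transcripts, which are not independent replicates, Pearson's r of the log2 fold changes was 0.699, 0.730 and 0.633 in these 3 pairs, and 0.606, 0.585 and 0.520 in simulations of unchanged tumours. The covariance was 1.65, 1.62 and 1.28, against 0.182 in the simulations for each pair. With the controls split between the 2 tumours over 10 splits, the mean r was 0.620, 0.641 and 0.544. With split controls the pairs shared on average 1824, 2393 and 1771 higher transcripts, where independent lists would share 760.6, 1094 and 819.

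The labels were then checked against the profiles by finding, for each library, the library with the highest Spearman correlation over the tested transcripts. The nearest library had the same tissue type in 26 of 32 cases, where permuted labels gave 8.30 on average (permutation p = 1e-05, the smallest that 100000 permutations can give). Mean correlations within and between types were 0.807 and 0.695 for clear cell sarcoma, 0.783 and 0.699 for osteosarcoma, 0.848 and 0.728 for synovial sarcoma, and 0.843 and 0.668 for the controls. The 6 exceptions were the clear cell sarcoma Rosa26CreER 2 and the synovial sarcoma 44, which were nearest to each other (rho 0.893), the osteosarcoma Col1Cre 31 and the clear cell sarcoma TATCre N178-Lleg, which were nearest to synovial sarcomas, the control Chest3, nearest to the clear cell sarcoma TATCre N123-Rleg, and the osteosarcoma Prx1Cre 42, nearest to the control Bone3 (rho 0.825). Over the 13626 transcripts of 100 bases or more, 31 of 32 were nearest to a library of their own type, the exception being Prx1Cre 42. With no filter on low values, 16 of 32 were.

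Within clear cell sarcoma, the initiating Cre groups were compared to ask how far the tumours differ by the way they were started. All 4 TATCre titles carry a word that may name a site (RLN, Rleg, Lleg or Larm), and the other clear cell sarcoma titles carry none. A difference of site therefore cannot be told apart from one of initiating Cre. A moderated F test over the 4 groups called 1633 of 15195 transcripts. The group mean was highest in TATCre for 723 of these, in Rosa26CreER for 386, in Bmi1IRESCreERT2 for 321 and in Prx1CreERT2 for 203. TATCre tumours differed from Rosa26CreER tumours at 1928 transcripts, 840 higher and 1088 lower, and at 1271, 699 higher and 572 lower, when the 2 TATCre libraries that share N123 were averaged. They differed from Bmi1IRESCreERT2 tumours at 1761, 1129 higher and 632 lower. Against Prx1CreERT2 they differed at 429, 273 higher and 156 lower. Rosa26CreER and Prx1CreERT2 differed at 296 transcripts, and Prx1CreERT2 and Bmi1IRESCreERT2 at 152. Rosa26CreER and Bmi1IRESCreERT2 differed at 4 transcripts, all lower in Rosa26CreER, and at 2 with N123 averaged, although 2023 had an unadjusted p under 0.05. None of the 4 printed transcripts passed the F test (limma adjusted p = 0.0967 for uc007equ.1, 0.132 for uc009czd.1, 0.653 for uc007gaj.2 and 0.214 for uc009kic.1). Of the 13 libraries, 9 were nearest to a clear cell sarcoma of their own Cre group, where permuted labels gave 3.004 on average (permutation p = 0.0022).

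Single libraries moved these counts, which rest on groups of 2 to 5. The F test count was 849 without Rosa26CreER 3, 830 without TATCre N123-RLN, 2470 without N178-Lleg, 759 without N179-Larm, 886 and 901 without Prx1CreERT2 2 and 4, and 1030 without Bmi1IRESCreERT2 1. The TATCre against Rosa26CreER count was 980, 865 and 966 without Rosa26CreER 2, 3 and 4, and 918, 1155, 3212 and 728 without TATCre N123-RLN, N123-Rleg, N178-Lleg and N179-Larm. Its direction turned as well, from 43.6% of the calls higher in TATCre to 53.6%, 52.9% and 50.6% without Rosa26CreER 2, 3 and 4, and to 56.2%, 56.5% and 56.7% without TATCre N123-RLN, N123-Rleg and N179-Larm. The TATCre against Bmi1IRESCreERT2 count was 204 without Bmi1IRESCreERT2 1 and 1043 without 2, and 1007, 2783 and 811 without TATCre N123-RLN, N178-Lleg and N179-Larm. The TATCre against Prx1CreERT2 count was 66 without either Prx1CreERT2 library and 895 without TATCre N178-Lleg, with the direction turned (416 higher and 479 lower). The Rosa26CreER against Prx1CreERT2 count was 41 and 27 without Prx1CreERT2 2 and 4, and 161 without Rosa26CreER 3. The Prx1CreERT2 against Bmi1IRESCreERT2 count was 27, 20 and 89 without Prx1CreERT2 2, Prx1CreERT2 4 and Bmi1IRESCreERT2 1. The Rosa26CreER against Bmi1IRESCreERT2 count of 4 became 1, 155 and 1 without Rosa26CreER 1, 2 and 5, and 0 and 31 without Bmi1IRESCreERT2 1 and 2.

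The direction of 2 of the 3 TATCre comparisons also moved with the scaling. Against Rosa26CreER, quantile normalization shifted the median log2 fold change by 0.28 and gave 1082 higher and 578 lower transcripts, and median ratio scaling gave 984 higher and 880 lower. Against Bmi1IRESCreERT2, median ratio scaling gave 759 higher and 833 lower, whereas quantile normalization gave 1097 higher and 498 lower. Against Prx1CreERT2, more transcripts were higher than lower under both scalings, though not without N178-Lleg (above), with 281 and 194 after quantile normalization and 275 and 158 after median ratio scaling. The calls that involve the 2 Prx1CreERT2 libraries were largely calls of transcripts listed at 0. Of the 296 calls against Rosa26CreER, 252 (85.1%) were listed at 0 throughout 1 of the 2 groups, against 20.1% of the tested transcripts. The share was lower against TATCre, with 239 of 429 calls (55.7%, against 20.9% of those tested). Against Bmi1IRESCreERT2 it was 138 of 152 (90.8%, against 21.1%). A filter to transcripts above 0 in every clear cell sarcoma library drops all transcripts listed at 0 throughout a group, so lower counts follow from it by construction. With that filter there was 1 call for Rosa26CreER against Prx1CreERT2, 92 for TATCre against Prx1CreERT2 and 0 for Prx1CreERT2 against Bmi1IRESCreERT2. With limma voom on the recovered reads the counts were 25, 186 and 1. Voom covered only transcripts with recovered reads. It therefore could not call 60 of the 296, 78 of the 429 and 53 of the 152 main calls, which also lowers its counts by construction.

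**Figure D3:**
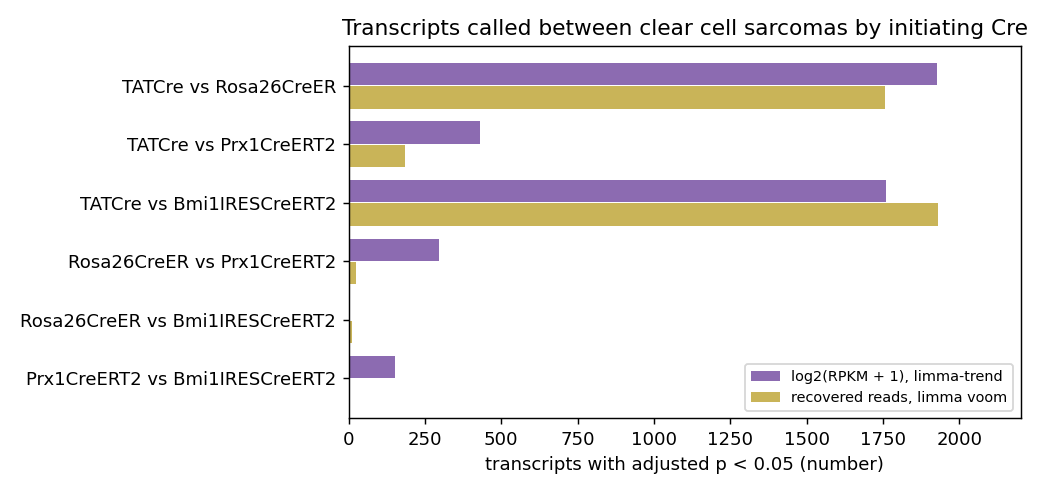
Transcripts called in each of the 6 comparisons of initiating Cre groups within clear cell sarcoma, higher and lower together (bars, limma adjusted p under 0.05). Paired bars give the main test on the deposited RPKM (15195 transcripts tested) and limma voom on the recovered reads (14738 tested). In the main test, the TATCre comparisons with Rosa26CreER (1928) and Bmi1IRESCreERT2 (1761) stand above those that involve Prx1CreERT2.

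The osteosarcomas were compared by the Cre named in their titles, 4 with Col1Cre and 3 with Prx1Cre. Limma called 0 of 12623 transcripts, voom on the recovered reads also called 0, and 570 (4.52%) had an unadjusted p under 0.05. The lowest adjusted p was 0.730. In simulated data of this size, in which few transcripts changed, 0 of 100 transcripts changed 4-fold were recovered. A difference of that size in so few transcripts would therefore be missed here. Groups of this size can yield calls, since another split of the same libraries gave 54. The count was 16 without Prx1Cre 28-thigh, 10 without Col1Cre 22 and 2 without Col1Cre 26-Right.

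**Figure D4:**
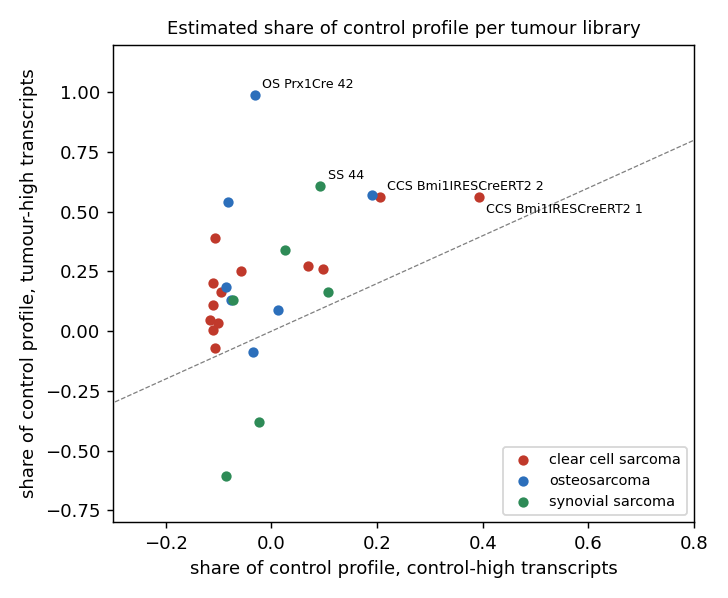
Share of the control profile estimated in each tumour library from transcripts higher in the controls (x axis) and from transcripts higher in its tumour type (y axis), where 0 is the mean of the other tumours of that type (for Bmi1IRESCreERT2, those of the other Cre groups) and 1 the mean of the controls, with equal values on the dashed line. The osteosarcoma Prx1Cre 42 lies at -0.03 on the x axis and 0.99 on the y axis, and the 2 Bmi1IRESCreERT2 clear cell sarcomas at 0.39 and 0.56 and at 0.20 and 0.56.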

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

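All tests of outlying samples followed a rule set in advance, and 8 tests below were chosen after their result had been seen in part: depth in the first and second pattern, another tumour type as the label (2 tests), a plain minimum, transcript length, and both tests of the third pattern. The count of members of the osteosarcoma set was also added then. Among 58 sets of values tested for 1 sample far from the rest of its group, 13 had one, where chance gives 2.9. Linear RPKM values are skewed, which adds to this number. A library that alone is above 0 in its group also adds to it, since it passes by construction.

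The osteosarcoma library Prx1Cre 42 stood apart in 3 values, with a mean log2(RPKM + 1) of 2.88 for the osteosarcoma set (other osteosarcomas 4.62 to 5.38), 11.7% of its RPKM in the control set (others 1.55% to 4.72%, while its mean log2(RPKM + 1) of that set, 3.28, lies within the others' 1.84 to 3.35) and 13288 RPKM of uc007gaj.2 (others at most 862). The clear cell sarcoma Rosa26CreER 2 stood apart from the other Rosa26CreER tumours with a mean of 4.47 for the clear cell sarcoma set (others 4.79 to 4.89) and with 712 RPKM of uc007gaj.2 (others listed at 0). The osteosarcoma Col1Cre 26-Right had 4.72% of its RPKM in the control set (other Col1Cre libraries 1.91% to 1.97%) and 14.1 RPKM of uc009kic.1 (others at most 2.26). The osteosarcoma Col1Cre 22 had 104.5 RPKM of uc007equ.1 (other osteosarcomas at most 10.3). The osteosarcoma Prx1Cre 28-thigh had 36.3 RPKM of uc009kic.1 (others at most 14.1). The synovial sarcoma 39-9 had 53200 RPKM of uc007gaj.2 (others at most 9138) and 1660 of uc009kic.1 (others at most 217). The clear cell sarcoma Rosa26CreER 3 had 0.189 RPKM of uc009kic.1 and the other Rosa26CreER libraries were listed at 0. Where all others are listed at 0, any value above 0 passes the rule. This value and the uc007gaj.2 value of Rosa26CreER 2 are therefore no sign that these libraries differ.

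The first pattern weighed is that the osteosarcoma Prx1Cre 42 has a low mean of the osteosarcoma set and lies nearest to a control. At most a small part of the set stays high in it, not far above the highest control. With the set chosen without the library in question, 55 of 473 members (11.6%) lay above all libraries of other types in Prx1Cre 42, against 47.3% to 70.5% in the other osteosarcomas and 0.325% to 8.08% in the controls. A control share was estimated from transcripts higher in osteosarcoma (0.99) and from transcripts higher in the controls (-0.0313). Normal tissue like the controls would ideally give 2 equal shares, and these differ by 1.02. In the other osteosarcomas the shares differ by 0.0521 to 0.624, so unequal shares alone do not decide this. RNA like the controls would also raise the share from transcripts higher in the controls. That share lies within the -0.0862 to 0.191 of the other osteosarcomas, which argues against a large part of such RNA. A control under another label would give 2 shares near 1, but the lower is -0.0313. The 6 controls tested the same way gave 0.709 to 1.09 for it. Its depth of 10.8 M reads lies within the 9.33 to 11.98 M reads of the other osteosarcomas, which argues against depth. An exchange with a typical tumour of another type of the series is also argued against. With the sets chosen without this library, its mean was 1.32 for the clear cell sarcoma set (clear cell sarcomas 4.15 to 4.89, other libraries 1.27 to 2.23) and 1.33 for the synovial sarcoma set (synovial sarcomas 3.23 to 4.66, other libraries 0.932 to 1.99). Its mean of the osteosarcoma set, 2.88, also lies within the 1.62 to 2.98 of libraries of other types. Such means therefore cannot exclude an atypical tumour of another type. That, a tumour of another composition, a normal tissue unlike these controls or a sample from outside the series may account for it. These stay open, untested.

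The second pattern is the calls that involve the 2 Prx1CreERT2 libraries. Of the 296 calls against Rosa26CreER, 182 were listed at 0 in both Prx1CreERT2 libraries, and the reads expected there from the Rosa26CreER mean had a median of 17.97 (quartiles 13.4 and 24.96), with 50 or more in 14 (7.69%), which is consistent with low values listed at 0 by the unknown rule of the table. A plain minimum of reads is excluded as that rule, since 1144 values of 1 to 9 reads are listed in these 2 libraries. Another 70 were listed at 0 in every Rosa26CreER library. Transcripts under 100 bases made up 18.9% of the 296 calls, against 9.81% of the tested transcripts. No length was recovered for 60 calls, and with all of these counted as short the share would be 39.2%. Very short transcripts therefore do not account for most of these 296 calls. Of the 429 calls of TATCre against Prx1CreERT2, 38 were short and 78 had no length. For Prx1CreERT2 against Bmi1IRESCreERT2, 30 of 152 calls were short and 53 had no length. Short transcripts could be most of the calls there, so that comparison is not decided. By its test, depth cannot be told apart from the other explanations. The depths of 8.12 and 8.23 M reads lie near the lower end of the other clear cell sarcomas (8.11 to 11.5) without lying below all of them. The expected reads above are at the depth of these 2 libraries, where sampling alone would give 0 in 0.00454% of values with 10 expected reads. This argues against sampling at lower depth alone, but an effect of depth through the unknown rule was not tested. A biological effect of the Prx1CreERT2 start stays open, untested.

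The third pattern is the 632 transcripts lower in TATCre than in Bmi1IRESCreERT2 tumours. Of these, 347 (54.9%) were also higher in the controls than in the Rosa26CreER and Prx1CreERT2 tumours, which are in neither group of this comparison, against 13.8% of the tested transcripts, and 103 were lower in the controls. Of the 1129 transcripts higher in TATCre, 724 (64.1%) were lower in the controls and 29 higher, against 36.9% of the tested transcripts lower in the controls. Both control shares were higher in the 2 Bmi1IRESCreERT2 libraries (0.39 and 0.56 in library 1, 0.20 and 0.56 in library 2) than in any TATCre library (at most -0.06 and 0.39). Their tumour means differ, however. The 2 Bmi1IRESCreERT2 libraries were left out of the mean for their own shares and kept in that for the TATCre libraries. This can widen the gap, by an amount that was not tested. Normal tissue like the controls would ideally give 2 equal shares. These differ by 0.17 in library 1 and by 0.356 in library 2. The shares of the other clear cell sarcomas differ by 0.0379 to 0.498, so unequal shares alone do not decide this either. More RNA of normal tissue therefore cannot be told apart from other explanations. Most calls were lost without either library. Without Bmi1IRESCreERT2 1 there were 45 lower calls (30 shared, 4.75% of 632) and without Bmi1IRESCreERT2 2 there were 429 (195 shared, 30.9%), in fits in which the lone library is assumed to vary like the other groups. The TATCre libraries moved the count as well, to 265, 372, 1339 and 250 lower calls without N123-RLN, N123-Rleg, N178-Lleg and N179-Larm, and to 395 with N123 averaged. An effect of 1 library cannot be told apart from the loss of a replicate in a group of 2. A biological difference by initiating Cre stays open, since the design confounds it with the makeup of these 2 tumours.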

How the results depend on the processing

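Tests with voom, transcripts above 0 in every library, a length of at least 100 bases, Chest1 and Chest2 averaged, 4 libraries left out, Pearson correlation and other filters for the nearest library were chosen after the data had been seen. The counts are of called transcripts, and the cause of a change was not tested unless said. All 6 comparisons of tissue types kept calls in both directions under every alternative. Single transcripts were tried only with a pseudocount of 0.1 and with quantile normalization. Only the leading transcripts of each comparison under the naming rule were taken. Of the 92 alternative values for these 46 tests, 91 kept direction and call, 1 lost the call and 0 reversed. The naming rule takes the largest changes among calls without overlap between groups, so these values say little about other transcripts.

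With a pseudocount of 0.1, Rosa26CreER against Prx1CreERT2 gave 470 calls. With no filter, Rosa26CreER against Bmi1IRESCreERT2 gave 10, and the nearest library was of the same type in 16 of 32. With an RPKM filter of 5, the synovial sarcoma set had 433 transcripts, Rosa26CreER against Bmi1IRESCreERT2 had 0 (limma, where 2023 had an unadjusted p under 0.05 at a filter of 1) and Prx1CreERT2 against Bmi1IRESCreERT2 had 94. Quantile normalization gave 410 in the synovial sarcoma set and 7 for Rosa26CreER against Bmi1IRESCreERT2, and median ratio scaling gave 482 and 9. Library weights gave 3050 in the F test, 3604 for TATCre against Rosa26CreER, 1911 against Prx1CreERT2 (1009 higher and 902 lower), 902 against Bmi1IRESCreERT2 (684 higher and 218 lower), 877 for Rosa26CreER against Prx1CreERT2 and 1 against Bmi1IRESCreERT2. Averaging libraries that share a title number, which leaves fewer samples, gave 1129 for clear cell sarcoma against synovial sarcoma, 4254 for synovial sarcoma against the controls, 2094 for osteosarcoma against synovial sarcoma, and 291, 185 and 314 in the sets of clear cell sarcoma, osteosarcoma and synovial sarcoma. With all 32 libraries fitted, TATCre against Bmi1IRESCreERT2 gave 1160 (575 higher and 585 lower). With the 2 TATCre N123 libraries averaged, TATCre against Rosa26CreER gave 1271 (699 higher and 572 lower), and Rosa26CreER against Bmi1IRESCreERT2 gave 2.

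Voom on recovered reads gave 186 for TATCre against Prx1CreERT2, 25 and 10 for Rosa26CreER against Prx1CreERT2 and Bmi1IRESCreERT2, and 1 for Prx1CreERT2 against Bmi1IRESCreERT2, and it split TATCre against Bmi1IRESCreERT2 into 1010 higher and 920 lower. Main calls without recovered reads were outside this fit. Transcripts above 0 in every library, a smaller set, gave 5103, 2815 and 1957 for clear cell sarcoma against controls, osteosarcoma and synovial sarcoma, 2599 for osteosarcoma against synovial sarcoma, and 188, 177 and 230 in the 3 sets. Within clear cell sarcoma they gave 92 for TATCre against Prx1CreERT2, 1 and 0 for Rosa26CreER against Prx1CreERT2 and Bmi1IRESCreERT2, and 0 for Prx1CreERT2 against Bmi1IRESCreERT2, where 1753 had an unadjusted p under 0.05 with limma over all tested transcripts. Transcripts of at least 100 bases gave 162 for Rosa26CreER against Prx1CreERT2 and 23 for Prx1CreERT2 against Bmi1IRESCreERT2. Without the 4 libraries in doubt, TATCre against Rosa26CreER gave 1155 and Rosa26CreER against Bmi1IRESCreERT2 gave 8.

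Leaving out each library in turn gave 759 to 2470 in the F test, 728 to 3212 for TATCre against Rosa26CreER, 66 to 895 against Prx1CreERT2 and 204 to 2783 against Bmi1IRESCreERT2. The same gave 27 to 292 for Rosa26CreER against Prx1CreERT2, 0 to 155 against Bmi1IRESCreERT2, 20 to 182 for Prx1CreERT2 against Bmi1IRESCreERT2 and 0 to 16 for the osteosarcoma groups. Where 1 library was left in a group, it was assumed to vary like the other groups. The comparisons of tissue types and the 3 sets stayed within 1.5 times their count, with 6916 to 7966 for clear cell sarcoma against the controls.

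The replicate block used the title numbers that Rosa26CreER shares with Prx1CreERT2 (2 and 4) and with Bmi1IRESCreERT2 (1 and 2), with 1 residual degree of freedom. Deviations of same-numbered libraries correlated at 0.34 and -0.29. With 2 numbers each, these values cannot show whether same-numbered libraries share anything beyond the number. With the block the counts were 750, against 1203 in the same 4 libraries without it, and 0, against 0 without it (limma, 491 with an unadjusted p under 0.05 with the block). The gene list tests and their estimated correlation were not run, because the identifiers are not paired with names.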

Other observations

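The tests of other splits were set in advance, except those with averaged libraries, and these and the other values below were looked at after the data had been seen. The main axis of expression across the 32 libraries carried 25.3% of the variance, and the next 3 axes 13.4%, 12.7% and 7.47%. Tissue type took a median of 39.2% of a transcript's variance, where unrelated groups give a median of 7.97%, and initiating Cre took 44.1% within clear cell sarcoma, where unrelated groups give 22.1%. The 2 osteosarcoma groups took 9.72%, near the 9.55% of unrelated groups. Of the tested transcripts, 124 were at least 2-fold lower in clear cell sarcoma than in each other type, 194 in osteosarcoma and 5 in synovial sarcoma.

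The 2 Prx1CreERT2 tumours were the most alike pair of all 32 libraries by Spearman correlation over all tested transcripts (0.941), followed by the controls Chest1 and Chest2 (0.929). Over the 13626 transcripts of 100 bases or more, Chest1 and Chest2 were the most alike (0.961), and the controls Bone3 and Chest4 (0.940) and the synovial sarcomas 37-7 and 39-9 (0.935) also exceeded the Prx1CreERT2 pair (0.933). By recovered reads Chest1 and Chest2 were the closest pair within a group, with a chi-square of 1.83 per degree of freedom, and the 2 Prx1CreERT2 tumours were far from it, at 320.7. The labels do not say whether Chest1 and Chest2 came from 1 animal. Transcripts under 10 bases were 1.68% of those tested and carried 12.3% to 34.3% of a library's RPKM sum and 0.0576% to 0.161% of its reads, so they weigh far more in sums and shares of RPKM than in reads.

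The real grouping was compared with other splits of the same libraries into groups of the same sizes, the real one included, with 100 splits for each result below except the osteosarcoma groups, which have 35. The other initiating Cre results involve groups of 2 libraries and were not split. For the 6 comparisons of tissue types, the 3 sets and TATCre against Rosa26CreER, the real split was the only 1 of the 100 with a count as large, so a chance split is excluded at that level for these results. The real and the highest other count were 7772 and 2231 for clear cell sarcoma against the controls, 4854 and 276 against osteosarcoma, and 3403 and 700 against synovial sarcoma. They were 6041 and 3792 for osteosarcoma against the controls, 6579 and 4803 for synovial sarcoma against the controls, and 4179 and 1381 for osteosarcoma against synovial sarcoma. They were 482, 336 and 697 against 0 in each case for the 3 sets, and 1928 and 1032 for TATCre against Rosa26CreER. For the 2 osteosarcoma groups the real count was 0, which all 35 splits reach whatever the data, so the splits decide nothing about it. The highest other split, with Col1Cre 22 placed among the Prx1Cre libraries, gave 54 calls.

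The splits above treat libraries that share a title number as separate. With these averaged, the real and the highest other count were 7803 and 357, 4850 and 448, and 1129 and 311 for clear cell sarcoma against the controls, osteosarcoma and synovial sarcoma. They were 4254 and 71 for synovial sarcoma against the controls (84 splits), 2094 and 794 for osteosarcoma against synovial sarcoma, and 291 and 0, 185 and 2, and 314 and 213 for the 3 sets. For TATCre against Rosa26CreER they were 1271 and 571 (56 splits). For osteosarcoma against the controls, 2 of 100 splits gave as many as the real 6064, the other being the split that places the osteosarcoma Prx1Cre 42 with the 6 controls (6278). Under 5% of the splits reached the real count in each case.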
